A study of Rattus norvegicus with 111 samples.

How the data were processed

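RNA from maternal and fetal liver was assayed with the rat whole-transcriptome TempO-Seq panel, which per the labels' protocols holds 22253 probes for 20924 genes. The authors deposited one table per chemical with estimated counts per gene and library, not normalized. The submitters' processing notes name Partek, STAR 2.7.8a, DESeq2, R and the genome build mRatBN7.2. They do not say which tool made which step of the tables. Each table listed 20311 genes, and 12.2% of the values in the PFO5DoA table and 11.8% in the PFO4DA table had decimals. The deposited estimated counts were rounded to whole numbers before any test. No reference genome was used here.

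Groups were taken from the sample labels, through the dam identifier that opens each column name. Each dam but 1 had 2 libraries, 1 of maternal and 1 of fetal liver, and the column names do not say which is which. The remaining dam (dam 2286) had a maternal library alone. The life stage of the other columns was not inferred from its order, its well or its values. The tests planned per life stage, and the test between life stages, are therefore not reported here, and the dam was the unit of every test. To give both livers the same weight, the larger of a dam's 2 libraries was thinned at random with a fixed seed to the total of the smaller, and both were summed. This departs from the plan, which was to test each library as deposited. It was decided after the library totals were seen and before any test was run. A fold change is that of the summed livers, so a change in a single liver is diluted by the other. Of the 56 dams, 54 were used. A control dam of PFO5DoA (dam 2279) was left out because 1 of its libraries had 45505 counts, under 0.25 of the median of its table, and a dam at 30 mg/kg/d PFO5DoA (dam 2286) because it had a single library. Leaving out libraries of so low a total had been foreseen as an alternative only, and was taken into every fit after the totals were seen. The 0.1 mg/kg/d PFO5DoA group of 2 dams was left out of the tests, as in the study per the labels. All columns of both tables were mapped to dams.

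Each dose was compared with the controls of its chemical in one fit over all analysed doses, with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr by dose, estimateDisp, robust glmQLFit and glmQLFTest). A gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05. The trend used log2(dose + 1). The difference between chemicals was the interaction contrast in a joint fit of both tables. The 2 tables were scaled together for that fit, and a constant difference between them cancels in the contrast. Intervals for that difference are 1.96 standard errors on either side. Levels are TMM-scaled CPM per dam with the SD over dams. For a gene at 0 in a group the floor was 3 counts over the group, and for 1 to 3 counts an exact 95% interval of the ratio was computed. Dams are separate animals, and each value of n counts dams.

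The genes to be named were fixed before the data were examined as those with the largest rises and falls at the highest dose, among genes with an adjusted p under 0.05, a mean of at least 5 CPM in the dose group or its controls and every treated replicate on the same side of the control mean. The gene lists fixed at the same time (30 lists) and the genes chosen by symbol could not be looked up, since 0 of the 20311 IDs matched a name in the reference table used here. With IDs alone, the 2 largest rises and the 2 largest falls at 30 mg/kg/d PFO5DoA are given and followed through every other comparison.

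Every pair of libraries within a dose group differed by more than sampling noise, with a chi-square per degree of freedom of at least 14.7 over genes with a summed count of 20 or more, so no library was counted as a duplicate. The steps were tested on simulated data drawn from the real means, spreads and totals, with 200 genes changed per simulation in 5 simulations. For 30 mg/kg/d PFO5DoA, 85.5% of 4-fold, 58.2% of 2-fold and 12.2% of 1.5-fold changes were recovered among about 12109 genes, and 4.43% of the calls were false. For 30 mg/kg/d PFO4DA the shares were 91.8%, 72.5% and 36.7% among 11768 genes, with 4.84% false calls. For the difference between chemicals at 30 mg/kg/d they were 79.7%, 42.1% and 7.16% among 11813 genes, with 6.55% false calls. For the trend of PFO5DoA, 93.0%, 70.4% and 31.0% were recovered among about 12110 genes, and for that of PFO4DA 94.2%, 79.1% and 54.9% among about 11767 genes. The simulated genes were drawn independently, without dam runs or other structure shared by dams. They also held far fewer changed genes than were called at 30 mg/kg/d PFO5DoA. These shares show that the steps work and need not hold for the real data.

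Other settings, fixed before the files were read, were DESeq2 1.42.0, another scaling of the libraries (RLE), no filter on low counts, the dam run as a covariate, each dose with its controls alone, the 0.1 mg/kg/d dams kept in the fit, a minimum fold of 2, the rank of the dose, the replicate number of the titles as a block and each dam left out in turn. A dam took the number of its maternal title in one blocked fit and that of its fetal title in another. Alternatives added after the data were seen were the sum of the counts as deposited, the same with the dam of the failed library kept, another random thinning, limma 3.58.1 on the mean log2 CPM of a dam's libraries and the dams of each run alone. Splits of the dams that keep the number of dosed dams in each run were also added. Overlaps of lists between chemicals are given beside the product of the list lengths divided by the genes tested in both.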

Results

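The series measured liver gene expression in pregnant Sprague-Dawley rats and their fetuses after repeated oral dosing with one of 2 perfluoroalkyl ether carboxylic acids, PFO4DA or PFO5DoA. PFO5DoA is the longer homologue of PFO4DA, with a single further difluoromethoxy unit in the chain. The stated purpose was to compare dose-responsive expression changes in maternal and fetal liver. Dams were dosed from gestational day 18 to 22, and the controls received the vehicle at 0 mg/kg/d. Expression was measured with TempO-Seq, a targeted assay in which pairs of probes are ligated on each RNA and the ligated products are sequenced and counted. In all, 111 libraries came from 56 dams, 56 from maternal and 55 from fetal liver. The PFO5DoA table held 51 libraries from 26 dams and the PFO4DA table held 60 libraries from 30 dams, each chemical with its own controls.

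For dams with 2 libraries the column names gave the dam but not whether a library was of the maternal or the fetal liver, so every value below describes both livers of a dam together and no comparison of the life stages is made. A dam's 2 libraries entered with equal depth and the dam was the replicate. For PFO5DoA, 5 control dams, 3 dams each at 0.3, 1 and 30 mg/kg/d and 4 dams each at 3 and 10 mg/kg/d were analysed. For PFO4DA, 6 control dams and 4 dams each at 0.3, 1, 3, 10, 30 and 62.5 mg/kg/d were analysed. Apart from 1 control library with 45505 counts, totals per library lay between 7132999 and 15254939 counts for PFO5DoA and between 7192234 and 12189307 counts for PFO4DA. The equal-depth sum per dam lay between 14265722 and 24854154 counts for PFO5DoA and between 14385716 and 22120400 counts for PFO4DA. The tables identified genes by Ensembl gene ID and did not pair the IDs with names, so genes are described here as sets that rose or fell, with 4 IDs as examples.

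The first comparison asked which genes PFO5DoA changed at each dose. At 0.3 mg/kg/d, 15 of 12268 genes changed and all 15 rose, by a median of 1.29 on the log2 scale. At 1 mg/kg/d, 150 genes rose and 24 fell. The rises at that dose had a median log2 fold change of 1.23, and 103 of them were at least 2-fold, whereas the falls had a median of -0.76 and 7 of them were at least 2-fold. At 3 mg/kg/d, 392 genes rose and 273 fell. The number of genes that fell drew level with the number that rose at the higher doses, with 1035 rises and 1001 falls at 10 mg/kg/d and 2291 rises and 2289 falls at 30 mg/kg/d. The changed genes at 30 mg/kg/d made up 37.3% of the genes tested, 808 rises and 1139 falls were at least 2-fold, and 105 rises and 99 falls were at least 8-fold. Across the 22 dams of all analysed doses, 2517 genes rose and 2494 fell with log2(dose + 1). All of these counts are at an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The count of 15 at 0.3 mg/kg/d was 8 when only that dose and its controls were fitted and 34 with DESeq2 (29 rises and 5 falls). It was 6 without dam 2269, 7 without dam 2263, 2270 or 2278 and 8 without dam 2280. The count of 174 at 1 mg/kg/d was 97 without dam 2272, 95 without dam 2273 and 311 with DESeq2 (223 rises and 88 falls). When only a dose and its controls were fitted, 112 genes changed at 1 mg/kg/d, 402 at 3 mg/kg/d and 1117 at 10 mg/kg/d. With a minimum fold of 2, 298 changed at 3 mg/kg/d and 712 at 10 mg/kg/d.

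**Figure D1:**
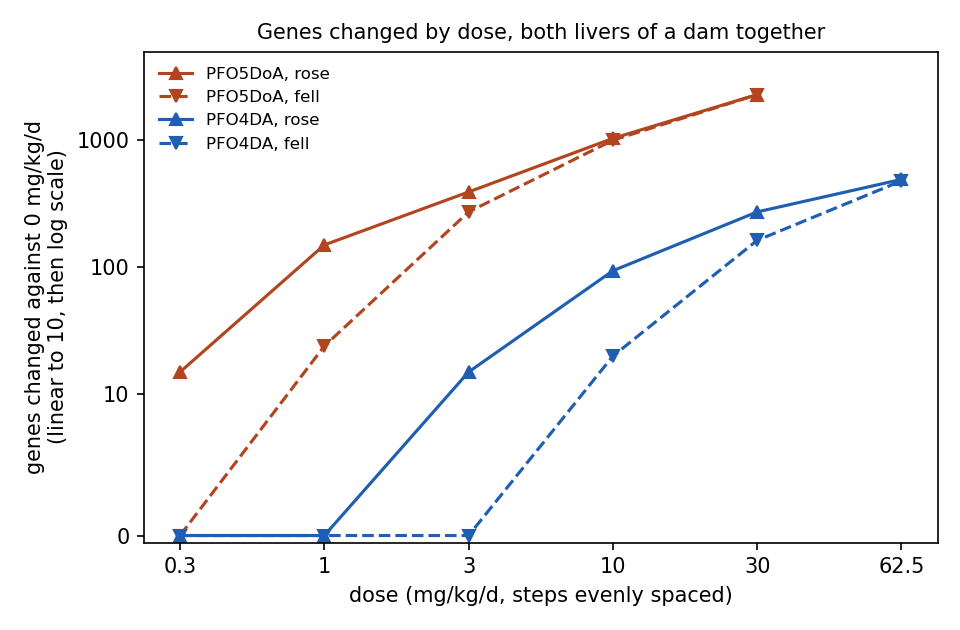
Number of genes that rose (solid lines, upward triangles) or fell (dashed lines, downward triangles) against 0 mg/kg/d at each dose of PFO5DoA (orange) and PFO4DA (blue); the vertical axis is linear to 10 and logarithmic above. PFO5DoA changed 15 genes at 0.3 mg/kg/d and PFO4DA changed 15 genes at 3 mg/kg/d, all of them rises, and the curves for rises and falls met at the highest dose of each chemical.

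The gene ENSRNOG00000062471 was among the 2 that rose most at 30 mg/kg/d PFO5DoA among genes of at least 5 CPM in either group. Its level was 9.81 ± 5.35 CPM (counts scaled by the TMM-adjusted total of the dam; SD, n = 5 dams) in the controls and 1699 ± 466 CPM (SD, n = 3 dams) at 30 mg/kg/d. The log2 fold change was 7.44 with a standard error of 0.53 (edgeR, adjusted p = 8.39e-09), and the level was higher in 3 of 3 dams than in any control dam. In each of these 3 dams 1 library had 2413 to 4610 CPM and the other 16.5 to 37.3 CPM, and in the controls 1 library had 10.1 to 41.0 CPM and the other 0.0852 to 3.11 CPM, so the level of a dam is not that of both livers. It had already risen at 1 mg/kg/d, with 52.3 ± 17.6 CPM (SD, n = 3 dams; edgeR, adjusted p = 0.00669), and stood at 91.5 ± 49.7 CPM (SD, n = 4 dams) at 3 mg/kg/d and 228 ± 71.1 CPM (SD, n = 4 dams) at 10 mg/kg/d. The gene ENSRNOG00000001794 had no counts in any of the 5 control dams, whose 95902234 counts in all set a floor of 0.0313 CPM at 3 counts over the group. At 30 mg/kg/d it had 635 counts over the group, or 11.6 CPM of the unadjusted total, which was at least 369-fold higher than the control floor (edgeR, adjusted p = 8.34e-05; present in 3 of 3 dams). These counts lay in a single library of each dam, at 11.6, 18.9 and 19.4 CPM, and the other library had 0, so the level over the group is not that of both livers. Of the 30 dams of all groups with counts of this gene, 0 had counts in both libraries. Floors and counting intervals cover counting error only. Both genes were chosen among those with an adjusted p under 0.05 at 30 mg/kg/d and every dosed dam above the control mean. These traits are therefore no further support.

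The genes ENSRNOG00000069588 and ENSRNOG00000010079 were the 2 that fell most at 30 mg/kg/d PFO5DoA among genes of at least 5 CPM in either group. Their choice required an adjusted p under 0.05 at that dose and every dosed dam below the control mean. ENSRNOG00000069588 was at 11.9 ± 3.33 CPM (SD, n = 5 dams) in the controls, 11.8 ± 4.93 CPM (SD, n = 3 dams) at 0.3 mg/kg/d and 2.63 ± 0.64 CPM (SD, n = 3 dams) at 1 mg/kg/d, where the fall passed the test (edgeR, adjusted p = 0.00805). At 30 mg/kg/d, 2 counts were left over the group, so that the level was 319-fold lower than in the controls, with an exact 95% counting interval of 88.0 to 2635 (edgeR, adjusted p = 6.65e-08; lower in 3 of 3 dams). Of the 51 dams with counts of this gene, 15 had counts in both libraries. The gene ENSRNOG00000010079 had 35.9 ± 32.5 CPM (SD, n = 5 dams) in the controls and 18.7 ± 4.15 CPM (SD, n = 4 dams) at 10 mg/kg/d, where the difference did not pass the test (edgeR, adjusted p = 0.435). It fell to 0.236 ± 0.085 CPM (SD, n = 3 dams) at 30 mg/kg/d, a log2 fold change of -7.21 with a standard error of 1.31 (edgeR, adjusted p = 0.000378; lower in 3 of 3 dams than in any control dam). In 4 control dams 1 library had 18.8 to 84.0 CPM of this gene and the other 0.159 to 0.682 CPM, and in control dam 2278 the libraries had 34.6 and 162 CPM. With limma on the mean log2 CPM of a dam's libraries, where each library has the same weight on the log scale, the log2 fold changes at 30 mg/kg/d were smaller. They were 5.91 for ENSRNOG00000062471, 3.25 for ENSRNOG00000001794, -3.22 for ENSRNOG00000069588 and -4.33 for ENSRNOG00000010079, each at an adjusted p under 0.05.

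**Figure D2:**
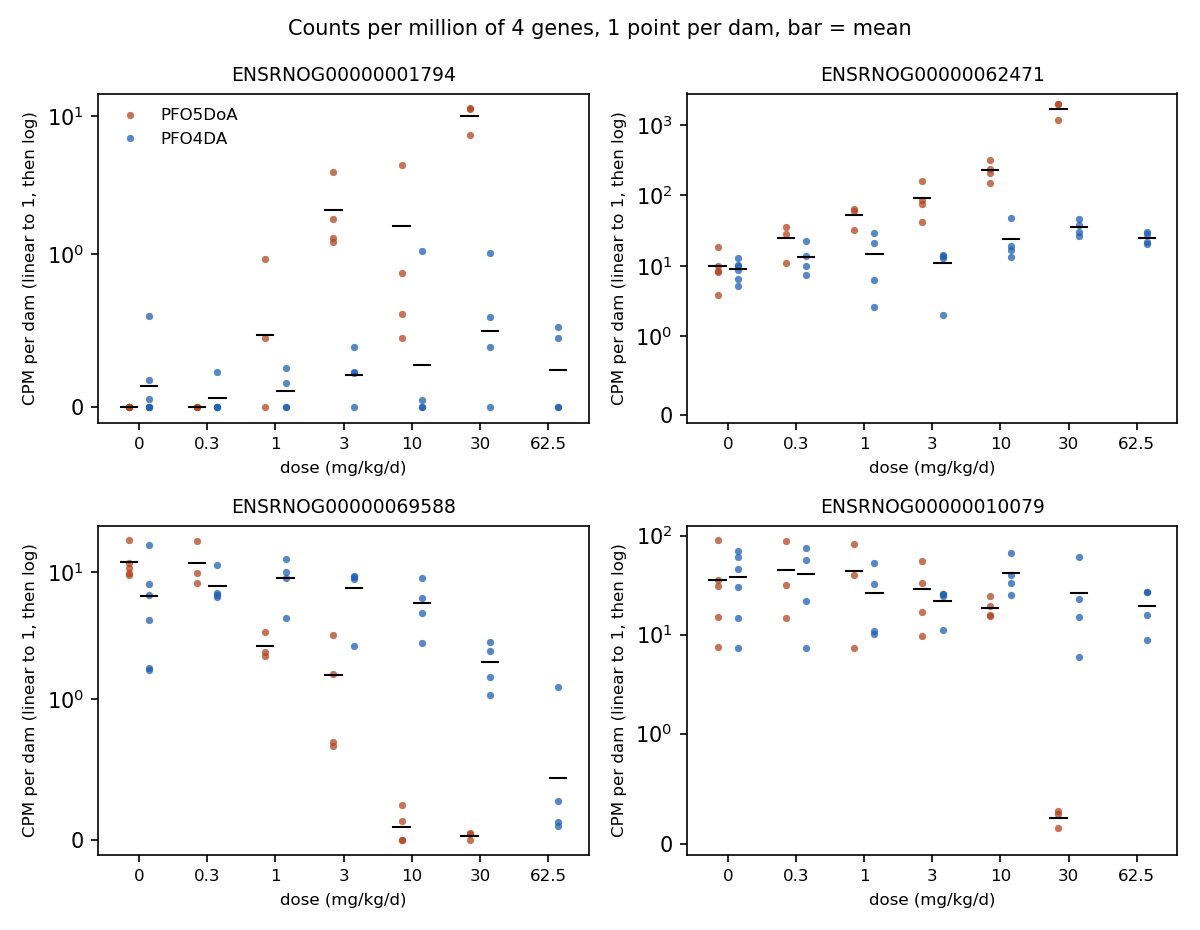
Levels (CPM) of 4 genes in each dam (1 point per dam, both livers together) by dose of PFO5DoA (orange) and PFO4DA (blue), with the mean of each group as a bar; the vertical axis is linear to 1 and logarithmic above. ENSRNOG00000062471 reached a mean of 1699 CPM at 30 mg/kg/d PFO5DoA against 35.1 CPM at 30 mg/kg/d PFO4DA, and ENSRNOG00000010079 fell to 0.236 CPM at 30 mg/kg/d PFO5DoA.

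The same comparison for PFO4DA gave a lower count of changed genes at each of the 5 shared doses. At 0.3 and 1 mg/kg/d, 0 of 11890 genes passed the edgeR test, with 695 and 512 genes at an unadjusted p under 0.05. DESeq2 called 2 genes at each of these doses, 2 falls at 0.3 mg/kg/d and 1 rise and 1 fall at 1 mg/kg/d, and limma on the mean log2 CPM called 0 at both. At 3 mg/kg/d, 15 genes changed and all 15 rose, by a median of 1.43 on the log2 scale. At 10 mg/kg/d, 94 genes rose and 20 fell, and at 30 mg/kg/d, 273 rose and 163 fell. At 62.5 mg/kg/d, 492 genes rose and 479 fell, which made up 8.17% of the genes tested, and 181 rises and 109 falls were at least 2-fold. Across the 30 dams, 829 genes rose and 802 fell with log2(dose + 1) in edgeR's quasi-likelihood test. The count of 15 at 3 mg/kg/d was 7 without dam 2294 or 2310, 6 without dam 2300, 5 without dam 2302 and 3 when only that dose and its controls were fitted. It was 5 with limma, 23 with DESeq2 and 2 or 6 with the replicate number of the maternal or fetal titles as a block. The count of 114 at 10 mg/kg/d was 71 without dam 2304, 57 with only that dose and its controls and 176 with DESeq2. With that block it was 69 or 67 and the count of 436 at 30 mg/kg/d was 297 or 287, and a minimum fold of 2 left 59 and 174 genes at these doses.

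Of the genes given as examples, ENSRNOG00000069588 fell under PFO4DA too. Its level was 6.43 ± 5.49 CPM (SD, n = 6 dams) in the controls and 0.44 ± 0.54 CPM (SD, n = 4 dams) at 62.5 mg/kg/d, a log2 fold change of -3.82 with a standard error of 0.73 (edgeR, adjusted p = 0.000983; below the lowest control in 4 of 4 dams). With limma that log2 fold change was -2.12. ENSRNOG00000062471 rose from 8.91 ± 2.7 CPM (SD, n = 6 dams) to 35.1 ± 8.59 CPM (SD, n = 4 dams) at 30 mg/kg/d (edgeR, adjusted p = 0.0235; higher in 4 of 4 dams than in any control dam). At 62.5 mg/kg/d its level was 25.2 ± 4.79 CPM (SD, n = 4 dams) and did not pass the test (edgeR, adjusted p = 0.0703). ENSRNOG00000010079 was at 38.1 ± 24.9 CPM (SD, n = 6 dams) in the controls and 19.5 ± 8.80 CPM (SD, n = 4 dams) at 62.5 mg/kg/d (edgeR, adjusted p = 0.475), and ENSRNOG00000001794 was at most 1.06 CPM in every PFO4DA dam.

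The next comparison asked whether the 2 chemicals differed at the doses they shared, as the difference between their log2 fold changes against their own controls. At 30 mg/kg/d, 2337 of 12577 genes differed, 1129 with a higher and 1208 with a lower log2 fold change under PFO5DoA. At 10 mg/kg/d, 613 genes differed, 275 higher and 338 lower under PFO5DoA. At 3 mg/kg/d, 103 genes were higher and 43 lower, and at 1 mg/kg/d, 57 were higher and 3 lower. At 0.3 mg/kg/d, 1 gene differed, which has no name in the tables. These counts are at an adjusted p under 0.05 in edgeR's quasi-likelihood test of the interaction. Leaving out 1 dam moved the count at 30 mg/kg/d to 1362 (without dam 2288), at 10 mg/kg/d to 344 (without dam 2303), at 1 mg/kg/d to 34 (without dam 2273) and at 0.3 mg/kg/d to 2 (without dam 2264). With DESeq2 the count at 1 mg/kg/d was 112 and at 0.3 mg/kg/d 5, and with no filter on low counts it was 407 at 10 mg/kg/d. No gene differed at 0.3 mg/kg/d with limma, or with the replicate number of the maternal titles as a block.

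For ENSRNOG00000062471 the log2 fold change under PFO5DoA exceeded that under PFO4DA by 2.94 at 3 mg/kg/d, by 3.09 at 10 mg/kg/d and by 5.48 at 30 mg/kg/d. The approximate 95% interval of the difference at 30 mg/kg/d was 4.01 to 6.95 (edgeR, adjusted p = 1.2e-06), whereas at 1 mg/kg/d the difference of 1.69 had an interval of 0.26 to 3.11 and did not pass after adjustment (edgeR, adjusted p = 0.425). For ENSRNOG00000069588 the difference was -3.21 at 3 mg/kg/d (edgeR, adjusted p = 0.00747) and -6.75 at 10 mg/kg/d (edgeR, adjusted p = 1e-05), where 7 counts were left over the PFO5DoA group. For ENSRNOG00000010079 the difference at 30 mg/kg/d was -6.66 with an interval of -9.52 to -3.81 (edgeR, adjusted p = 0.00101). At 10 mg/kg/d that difference was -1.07 with an interval of -2.99 to 0.86, which holds differences in both directions (edgeR, adjusted p = 0.641). These genes were chosen for their large change at 30 mg/kg/d PFO5DoA, which enters the difference at that dose. The differences, intervals and adjusted p at 30 mg/kg/d are therefore biased by the choice and are no further support. Those at lower doses share the PFO5DoA controls with that choice.

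The genes changed by the 2 chemicals overlapped in the same direction more than independent lists of their lengths would, and the controls behind the lists were different dams. Of the 15 genes that rose at 0.3 mg/kg/d PFO5DoA, 9 were among the 15 that rose at 3 mg/kg/d PFO4DA, where 0.019 would be shared by chance, and 15 were among the genes that rose at 10 mg/kg/d PFO4DA. At 30 mg/kg/d of each chemical, 205 genes rose under both, against 51.1 for independent lists, 129 fell under both, against 31.2, and 2 changed in opposite directions, over 11816 genes tested in both. Between 3 mg/kg/d PFO5DoA and 30 mg/kg/d PFO4DA, 195 genes rose under both and 94 fell under both, against 8.77 and 3.72, and 0 changed in opposite directions. The log2 fold changes of all 11816 genes correlated across genes with a Pearson's r of 0.62 for that pair of doses and of 0.46 for 30 mg/kg/d of each chemical. Genes are not independent replicates, and no p is given for these correlations. With no filter on low counts the value for 30 mg/kg/d of each chemical was 0.13.

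**Figure D3:**
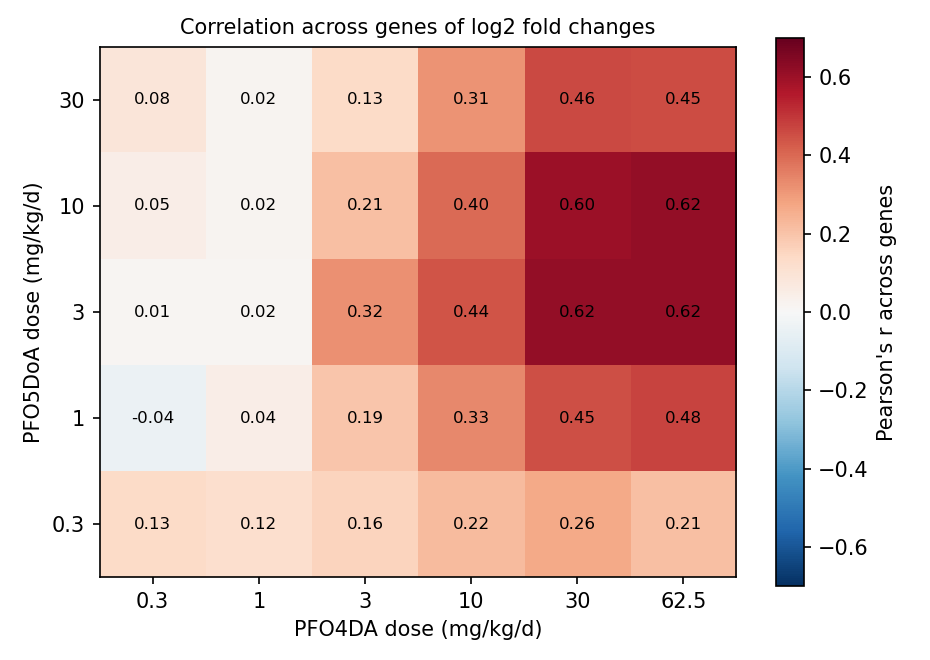
Pearson's r across 11816 genes between the log2 fold changes at each dose of PFO5DoA (vertical axis, mg/kg/d) and each dose of PFO4DA (horizontal axis, mg/kg/d), each against its own controls, with red for positive and blue for negative values. The highest values, up to 0.62, lay where 3 or 10 mg/kg/d PFO5DoA met 30 or 62.5 mg/kg/d PFO4DA.

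The dam identifiers fell into 2 runs for each chemical, each opening with its own controls, and the runs share no dam. At 10 mg/kg/d PFO5DoA the first run (2 dams) gave 1336 changed genes and the second run (2 dams) 405, against 2036 for both together. Of 1330 genes called in the first run and tested in both, 1184 had the same sign in the second run, and 289 were called in both, where 45.7 would be shared by chance. At 3 mg/kg/d PFO5DoA the second run gave 124 changed genes, and 89 genes were called in both runs against 4.76 by chance. At 30 mg/kg/d PFO4DA the runs gave 88 and 209 changed genes, all 88 of the first run had the same sign in the second, and 72 were called in both against 1.52 by chance. The 30 mg/kg/d PFO5DoA dams lay in the second run alone, where they gave 2430 changed genes against the controls of that run. The 62.5 mg/kg/d PFO4DA dams also lay in the second run alone, and the 0.3 and 1 mg/kg/d PFO5DoA dams in the first, where 0.3 mg/kg/d gave 3 changed genes and 1 mg/kg/d gave 141. At 3 and 10 mg/kg/d PFO4DA the first run (3 dams each) gave 1 and 36 changed genes, of which 1 and 34 had the same sign in the second run. The second run held 1 dam at each of these doses. Between the runs the log2 fold changes correlated across genes at -0.099 and 0.0866, against 0.397 at 30 mg/kg/d PFO4DA. The runs thus gave little agreement over all genes at 3 and 10 mg/kg/d PFO4DA, with 1 dam on the side of the second run. The 36 genes called in the first run at 10 mg/kg/d mostly kept their sign, so the low correlation does not speak against those calls.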

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

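All tests of explanations in this part, and the counts over other splits of the dams, were chosen after the results were seen. The number of splits was raised after smaller sets had been counted. In those smaller sets the share of splits as large as the real one was 0.05 or more for 1 mg/kg/d PFO5DoA and for the chemical difference at 30 mg/kg/d, and in the full sets it is under 0.05. These splits exchange dams freely between the 2 dam runs of a chemical, whereas the doses were not spread evenly over the runs. Splits within runs, which keep the number of dosed dams of each run, were therefore counted as well, after the other splits had been seen. The shares are not adjusted for the number of comparisons. A share under 0.05 makes chance less likely and does not exclude it.

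The 2 chemicals differed, by the test of the difference itself, in 1 gene at 0.3 mg/kg/d, 60 at 1 mg/kg/d, 146 at 3 mg/kg/d, 613 at 10 mg/kg/d and 2337 at 30 mg/kg/d. Among the genes given as examples, the difference in log2 fold change (PFO5DoA minus PFO4DA) of ENSRNOG00000062471 was 2.94 at 3 mg/kg/d, 3.09 at 10 mg/kg/d and 5.48 at 30 mg/kg/d. That of ENSRNOG00000069588 was -3.21, -6.75 and -6.56 at the same doses. ENSRNOG00000010079 differed by -6.66 at 30 mg/kg/d. ENSRNOG00000001794 differed by a fitted 8.81 at 30 mg/kg/d, a value that depends on the prior count because the PFO5DoA controls had no counts. The example genes were chosen for their change at 30 mg/kg/d PFO5DoA. Their differences at that dose are therefore biased by the choice and are no further support.

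More genes changed under PFO5DoA than under PFO4DA at 30 mg/kg/d, 4580 against 436. Depth does not account for it: with every dam thinned to 14265722 counts, the difference between chemicals still had 2203 genes at 30 mg/kg/d. The dam run within a chemical does not account for it either, since with a run term for each chemical 1990 genes differed. Against the controls of its own second run, PFO5DoA changed 2430 genes (3 dosed and 2 control dams). PFO4DA changed 209 in its own second run (2 dosed and 3 control dams). The chemicals share no run, so a difference between their runs that acts on the dose effect could not be tested. PFO4DA had more dams, and with 3 dosed and 5 control dams, as for PFO5DoA, it gave 254 to 422 genes over 24 choices of dams. A difference between the chemicals in potency remains as a hypothesis, and a bodyweight about 17% below controls in the 30 mg/kg/d PFO5DoA dams, which the labels record, was not tested as a cause and stays open beside it.

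Whether chance could give the counts was examined by refitting each dose with its controls over other splits of the same dams. For PFO5DoA the real split gave 8 genes at 0.3 mg/kg/d, 402 at 3, 1117 at 10 and 3322 at 30 mg/kg/d, against at most 2, 57, 394 and 4 in the others. Only 1 split, the real one, reached these counts among 56 (0.3 and 30 mg/kg/d) or 100 splits. Within runs it was 1 of 60 splits at 3 and 10 mg/kg/d, with at most 10 and 7 genes in the others, so that chance is unlikely at these doses. At 0.3 and 30 mg/kg/d the share was under 0.05 only with dams exchanged across runs. Within runs the real split was the highest of 20 and of 10, with at most 1 gene in the others. So few splits cannot give a share under 0.05. At 1 mg/kg/d PFO5DoA, 2 of 56 splits gave at least the real 112 genes. This share across runs is under 0.05 by a narrow margin that the smaller set did not give. Within runs 1 of 20 splits was as large and the others gave at most 1 gene, a share that is not under 0.05. The other gave 318, with control dams 2265, 2278 and 2280 on one side and all dosed dams with controls 2263 and 2264 on the other. That points to a structure among the control dams. It follows the dam run in part, as dams 2278 and 2280 are the run 2 controls and the rest are run 1 dams, and within run 1 alone 141 genes changed at that dose.

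For PFO4DA the real split gave 57 genes at 10 mg/kg/d, 319 at 30 and 983 at 62.5 mg/kg/d, against at most 7, 129 and 87 in the other splits, with 1 of 100 splits as large each. Within runs 2 of 80 splits reached the count at 10 mg/kg/d and the highest other gave 76, above the real one. At 30 and 62.5 mg/kg/d 1 of 100 and 1 of 35 did, with at most 129 and 3 in the others. The shares are under 0.05, so that chance is unlikely at these 3 doses. At 3 mg/kg/d, 4 of 100 splits gave at least the real 3 genes and the highest gave 253, with control dams 2293 and 2308 and dosed dams 2301 and 2315 together. That points to a structure of the samples larger than the effect of this dose. Within runs 3 of 80 splits gave as many, each with 3 genes. At 0.3 and 1 mg/kg/d the real split gave 0 genes, so all 100 splits were as large, and the highest others gave 209 and 14. The highest at 0.3 mg/kg/d set the 3 run 2 controls and control dam 2293 against control dams 2294 and 2295 and all dosed dams. Among the controls this follows the run in part, but the dosed dams of both runs lay on the same side. Within runs the counts at that dose were 0 in run 1 and 1 in run 2. The trends had 5011 (PFO5DoA) and 1631 genes (PFO4DA), against at most 28 and 1 under other orders of the doses. With 1 of 100 as large, chance is unlikely. With doses shuffled within runs it was again 1 of 100 for each, with at most 1724 and 29 in the others.

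For the difference between chemicals, doses were shuffled among the dams of each chemical. The real assignment gave 42 genes at 1 mg/kg/d, 113 at 3, 256 at 10 and 1627 at 30 mg/kg/d in fits of that dose and its controls, and 3, 3, 3 and 2 of 100 assignments gave as many. The highest others were 407, 364, 1005 and 2724 genes. At 3, 10 and 30 mg/kg/d each assignment that reached the real count had left the PFO5DoA doses as they were and shuffled the PFO4DA doses, so it carried the PFO5DoA effect. The highest at 3 and 10 mg/kg/d set PFO4DA control dams 2293 and 2308 with all dosed PFO4DA dams, and took the other PFO4DA controls as dosed. This reverses the PFO4DA effect in the contrast, so these counts alone cannot tell whether the controls have a structure of their own. The splits of single PFO4DA doses do point to one. Control dams 2293 and 2308 lay together, apart from the other controls, in the highest other split at 1, 3 and 30 mg/kg/d (14, 253 and 129 genes). In these splits dosed dams lay on both sides. At 0.3 and 10 mg/kg/d further controls lay with them. The splits share the same controls and are not independent. At 1 mg/kg/d the highest set apart control dams 2265, 2278 and 2280, the same split as for the PFO5DoA dose itself. The share is under 0.05 at these 4 doses, at 30 mg/kg/d only with the larger number of splits. With doses shuffled within runs, 9, 3, 1 and 9 of 100 assignments gave as many at 1, 3, 10 and 30 mg/kg/d, and the highest others gave 102, 145, 240 and 3223 genes. At 3 and 10 mg/kg/d the share was under 0.05 by both counts. As the doses of both chemicals were shuffled, a low share speaks against no dose effect of either chemical. It does not test whether the 2 chemicals had equal effects, which rests on the interaction test. Within runs the 1 and 30 mg/kg/d PFO5DoA dams have 20 and 10 splits, so that about 1 in 20 and 1 in 10 shuffles leave the PFO5DoA doses as they were and carry its effect, as the 2 highest at each of these doses did. A share under 0.05 was hardly within reach there, so the within-run shuffles do not test chance at 1 and 30 mg/kg/d. The shares under 0.05 at these doses rest on dams exchanged across runs. At 0.3 mg/kg/d the real assignment gave 0 genes, all 100 were as large, and the highest other gave 5 genes across runs and 363 within runs.

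Single dams stood apart from the rest of their group in 10 of 49 sets of dam values tested (a gene given as an example or the total counts, in 1 dose group). The test was Dixon's Q, the gap to the nearest dam as a share of the range. Its cutoffs give about 1 in 20 for normal values, which CPM near 0 are not. ENSRNOG00000001794 at 0.3 mg/kg/d PFO4DA, for 1, had 4 counts over the group. The excess over 1 in 20 is therefore not read as outlying dams. ENSRNOG00000069588 was at 17.6 CPM in control dam 2265 of PFO5DoA, against 9.46 to 11.7 in the other 4 controls. It was at 11.3 CPM in dam 2297 at 0.3 mg/kg/d PFO4DA against at most 6.84, at 2.62 in dam 2315 at 3 mg/kg/d against at least 8.80, and at 1.24 in dam 2319 at 62.5 mg/kg/d against at most 0.281. ENSRNOG00000001794 was at 4.43 CPM in dam 2284 at 10 mg/kg/d PFO5DoA against at most 0.874. It was at 0.594 in PFO4DA control dam 2308 against at most 0.176, at 0.231 in dam 2296 at 0.3 mg/kg/d against 0, and at 1.06 in dam 2304 at 10 mg/kg/d against at most 0.0505. At 3 mg/kg/d PFO4DA, ENSRNOG00000062471 was at 2.04 CPM in dam 2302 against at least 13.1, and ENSRNOG00000010079 at 11.1 CPM in dam 2301 against at least 24.4.

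Data outside the comparisons carried signal too. At 0.1 mg/kg/d PFO5DoA, 5 of 12682 genes changed with 2 dams, all rises (edgeR, 1295 genes at an unadjusted p under 0.05), and the tables do not name them. The single library of dam 2286 at 30 mg/kg/d PFO5DoA had 4415 CPM of ENSRNOG00000062471, against at most 41.0 CPM in the 11 control libraries. In the same library, which the labels give as maternal, ENSRNOG00000001794 was listed at 0. In each of the other 3 dams of that dose 1 library was also at 0, beside 11.6, 18.9 and 19.4 CPM in the other.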

How the results depend on the processing

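No fold change of a gene given as an example that passed its test changed sign under an alternative, but near-even numbers of rises and falls turned under several alternatives. For the PFO4DA trend (829 rises, 802 falls) DESeq2 gave 883 and 936, at 62.5 mg/kg/d PFO4DA (492 rises, 479 falls) it gave 553 and 581, at 10 mg/kg/d PFO5DoA (1035, 1001) limma gave 1018 and 1037, and for the chemical difference at 10 mg/kg/d (275 higher, 338 lower) limma gave 287 and 282. The trends stayed within 1.5 times of 5011 and 1631 genes under each alternative run, and so did the counts for the alternatives and doses not named here. Alternatives for the combination of a dam's libraries and the runs alone were chosen after the data were seen, and the cause of each move below was not tested unless the alternative itself tests fewer samples or genes. With DESeq2 the counts were 34 and 311 genes at 0.3 and 1 mg/kg/d PFO5DoA, 2 (both falls), 2 (1 rise, 1 fall), 23 and 176 at 0.3, 1, 3 and 10 mg/kg/d PFO4DA, and 5 and 112 for the chemical difference at 0.3 and 1 mg/kg/d. With no filter on low counts the chemical difference at 10 mg/kg/d had 407 genes, and the correlations across genes of 30 mg/kg/d PFO5DoA with 30 and 62.5 mg/kg/d PFO4DA fell to 0.1307 and 0.1656. With limma, 5 genes changed at 3 mg/kg/d PFO4DA and 0 differed between chemicals at 0.3 mg/kg/d. Limma, which was run on the averaged logs of both libraries, gave smaller log2 fold changes at 30 mg/kg/d PFO5DoA. These were 5.91 for ENSRNOG00000062471, 3.25 for ENSRNOG00000001794, -3.22 for ENSRNOG00000069588 and -4.33 for ENSRNOG00000010079. For ENSRNOG00000069588 at 62.5 mg/kg/d PFO4DA limma gave -2.12. With a dose and its controls alone, which leaves fewer dams to estimate the spread, 8, 112, 402 and 1117 genes changed at 0.3, 1, 3 and 10 mg/kg/d PFO5DoA, and 3 and 57 at 3 and 10 mg/kg/d PFO4DA. A minimum fold of 2 left 110, 298, 712 and 1947 genes at 1, 3, 10 and 30 mg/kg/d PFO5DoA, and 59, 174 and 290 at 10, 30 and 62.5 mg/kg/d PFO4DA. Run 1 alone, with fewer dams, gave 3 and 1336 genes at 0.3 and 10 mg/kg/d PFO5DoA and 1, 36 and 88 at 3, 10 and 30 mg/kg/d PFO4DA. Run 2 alone gave 124, 405 and 2430 genes at 3, 10 and 30 mg/kg/d PFO5DoA and 1 (a fall) and 209 at 0.3 and 30 mg/kg/d PFO4DA. The rise of ENSRNOG00000062471 at 62.5 mg/kg/d PFO4DA (adjusted p = 0.0703 with edgeR) passed the threshold under 4 alternatives, with adjusted p between 0.000307 and 0.04, and over all its alternatives the adjusted p lay between 0.000307 and 0.175.

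Leaving out each dam in turn gave 6 to 16 genes at 0.3 mg/kg/d PFO5DoA (lowest without dam 2269), 95 to 215 at 1 mg/kg/d (without dam 2273), 5 to 15 at 3 mg/kg/d PFO4DA (without dam 2302) and 71 to 152 at 10 mg/kg/d (without dam 2304). For the chemical difference it gave 1 to 2 genes at 0.3 mg/kg/d (highest without dam 2264), 34 to 72 at 1 mg/kg/d (lowest without dam 2273), 344 to 745 at 10 mg/kg/d (without dam 2303) and 1362 to 2561 at 30 mg/kg/d (without dam 2288). The replicate numbers of the titles, alike in both libraries of 46 of 56 dams, mark different dams in each group and did not pair them. Each dose was compared with its controls by the maternal and again by the fetal numbers, 22 comparisons in all. In 0 of them did every same-numbered pair correlate above 0.1 in its deviations from the group means (17 of 82 pairs did). A pair whose dams carry the same number in both titles enters these totals 2 times. With the number as a replicate block, 2 or 6 genes changed at 3 mg/kg/d PFO4DA (maternal or fetal titles), 69 or 67 at 10 mg/kg/d and 297 or 287 at 30 mg/kg/d, and the chemical difference at 0.3 mg/kg/d had 0 or 1 genes. The other counts stayed within 1.5 times. Alternatives per life stage, for the life stage difference and for the gene lists were not run, for want of the life stage of a column and of gene names. Depth limits the genes given as examples: 2 counts were left of ENSRNOG00000069588 at 30 mg/kg/d PFO5DoA and 0 of ENSRNOG00000001794 in its controls.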

Other observations

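The tests in this part were chosen after the data were seen. The responses to the 2 chemicals lined up at different doses. Genes changed at 1 mg/kg/d PFO5DoA had fold changes of nearly the same size at 62.5 mg/kg/d PFO4DA, with a slope of 0.975 on the log2 scale over 173 genes, and 0.0958 at 1 mg/kg/d PFO4DA. For the 651 genes changed at 3 mg/kg/d PFO5DoA the slope was 0.217 at 3 mg/kg/d PFO4DA, 0.686 at 30 and 0.783 at 62.5 mg/kg/d. Choosing the genes on the PFO5DoA side biases these slopes. The 5 genes that rose at 0.1 mg/kg/d PFO5DoA in 2 dams, by a median of 1.99 on the log2 scale, all rose at 10, 30 and 62.5 mg/kg/d PFO4DA, where their median log2 fold changes were 2.61, 3.55 and 4.04, against other controls. Of all genes called at any dose of PFO4DA, 15 of 1046 were first called at 3 mg/kg/d and 597 at 62.5 mg/kg/d. For PFO5DoA, 2837 of 4940 were first called at 30 mg/kg/d.

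Rises came before falls along the dose of each chemical in the counts of changed genes with edgeR. This did not hold in every alternative at low doses: at 0.3 mg/kg/d PFO4DA the 2 genes called by DESeq2 and the 1 gene called in run 2 alone fell, and at 1 mg/kg/d DESeq2 called 1 rise and 1 fall. At 0.3 mg/kg/d PFO5DoA some alternatives called falls beside more rises. DESeq2 called 29 rises and 5 falls, and the block of the fetal titles 14 and 2. With the dam run as a term there were 15 and 1, and with limma 16 and 1. For PFO5DoA the tables argue against limited power for falls as the whole account: among genes called at 62.5 mg/kg/d PFO4DA, whose controls are other dams, the ratio of the median rise to the median fall at 1 mg/kg/d PFO5DoA was 1.74, and 1.53 to 2.07 with 1 dam left out. It was 1.33 at 3 mg/kg/d, 1.08 at 10 and 0.903 at 30 mg/kg/d, against 1.11 at 62.5 mg/kg/d PFO4DA itself. For PFO4DA limited power stays open: among genes called at 30 mg/kg/d PFO5DoA the ratio at 10 mg/kg/d PFO4DA was 0.993 (0.571 to 1.07 with 1 dam left out) and at 30 mg/kg/d 0.928. It was 0.663 at 62.5 mg/kg/d (0.541 to 0.708), against 0.815 at 30 mg/kg/d PFO5DoA itself, so the ratio fell with dose for PFO4DA too, and the ranges with 1 dam left out overlapped. The falling genes of that list were the less abundant (median log2 CPM 3.61 against 4.37). Scaling of the libraries stays open for both chemicals, since the other scaling that was run moved few calls and so could not test it.

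The fold changes at 30 mg/kg/d PFO5DoA were less like those at 62.5 mg/kg/d PFO4DA than the fold changes at 3 and 10 mg/kg/d PFO5DoA were, with correlations across genes of 0.455, 0.615 and 0.616. With the dam run as a term they were 0.4398, 0.606 and 0.612, which argues against the run. Leaving out 1 PFO5DoA dam gave at most 0.468 for 30 mg/kg/d and at least 0.566 for the other doses, which argues against a single PFO5DoA dam. PFO4DA dams were left out for 30 mg/kg/d alone, again with at most 0.468, so a single PFO4DA dam was not tested for 3 and 10 mg/kg/d. Over 5707 genes of at least 10 CPM they were 0.5686, 0.770 and 0.734, which argues against noise in genes with few counts. With no filter on low counts the correlation for 30 mg/kg/d was 0.1656, and those for 3 and 10 mg/kg/d were not computed. A further response at 30 mg/kg/d PFO5DoA that PFO4DA did not evoke may explain the gap. Of the 656 genes called under both treatments, 324 rose under both, 308 fell under both and 24 changed in opposite directions. Poor health of those dams, with bodyweights about 17% below controls in the labels, was not tested and stays open.

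The libraries fell into 2 separate clusters along the first principal component of log2 CPM, which held 70.0% of the variance over 10294 genes in 110 libraries. One cluster held 54 libraries at 66.5 to 101 and the other 56 libraries at -87.8 to -61.3, and in each of the 54 dams with 2 usable libraries 1 library lay in each cluster. The single library of dam 2286, which the labels give as maternal, was at -76.6. No life stage was assigned to the other libraries from these values. Within a library the 10 genes with most counts held 13.4% to 38.7% of the counts for PFO5DoA and 22.3% to 35.1% for PFO4DA. The controls of run 2 differed from those of run 1 in 20 of 11667 genes for PFO5DoA (2 against 3 dams) and in 3 of 11144 genes for PFO4DA (3 against 3 dams) with edgeR.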
